A study of Mus musculus with 12 samples.

How the data were processed

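RNA from whole adult mouse testes was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript with probe sets spread along its length. Per the labels, spermatogenesis had been synchronized: neonatal mice of a mixed strain background received a compound that blocks the synthesis of retinoic acid, at 100 ug per g of body weight on each of 7 days, from 2 to 8 days postpartum. They then received 200 ug of retinoic acid at 9 days postpartum and recovered for 43 to 49 days, before the testes were taken for the arrays and for staging by morphology. The labels place 2 samples in each of 6 stage groups, XII-I, II-IV, IV-VI, VII, VIII-IX and IX-XI. They give no untreated control. They do not say whether the 2 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Per the labels, 100 ng of RNA was amplified with the Ovation kit and 3.75 ug of cDNA was fragmented and biotin labelled with the Encore kit.

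The authors deposited 1 table of intensity values per probe set, made with RMA (robust multi-array average, which corrects the background, quantile normalizes the arrays and summarizes the probes of a set) per the submitters' processing notes. Its version is not given in the sources used here. The deposited intensity values lay on a linear scale, from 24.97 to 21760, and array medians lay between 296.9 and 309.1. They were transformed to log2 before any test, and no value was added or removed. RMA makes the arrays' distributions nearly alike, so a change in the total RNA of a testis cannot be seen in these values. All changes are relative to the other transcripts on the array.

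Of 28853 probe sets, 21797 had 1 gene symbol in the array's annotation, 1613 had several and 5443 were not listed there. Gene names were compared with the RefSeq gene table of GRCm38.p6 through Entrez IDs. This changed 0 symbols, and 99 probe sets had an ID that the table lacked. Probe sets with several symbols or none were left out. For the 999 genes with more than 1 probe set, the set with the highest mean over the 12 arrays was kept, which left 19946 genes. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. The RefSeq table was used only for gene names and to tell which genes lie on the X and Y chromosomes. Probe sets of multicopy or closely related genes can read several copies, and this holds for Samt3, Cldn34c4, Hmgb1-rs17, Phf8-ps, Klk1b5, Spdye4a, Srsy, Ssxb2, Pou5f1 and the ribosomal protein genes. The precision of every value is limited by the number of arrays.

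Genes were tested with limma 3.58.1 in R 4.3.3. A model with 6 group means was fitted to all 12 arrays with lmFit and eBayes, which left 6 residual degrees of freedom. A moderated F test asked which genes differed among the 6 groups. Contrasts compared each group with the mean of the other 5 and each group with the group before it in the cycle. The p-values were adjusted by the Benjamini-Hochberg method over all genes in each test, at a threshold of 0.05. Gene lists were tested with limma's camera on the contrast of each group with the other 5, with a preset correlation of 0.01 between genes, and adjusted over 28 lists and 6 groups. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined.

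A total of 27 lists with 784 entries was fixed. They covered retinoid metabolism and signalling, undifferentiated and differentiating spermatogonia, meiotic initiation, pachytene and diplotene spermatocytes, meiotic division and M phase, DNA replication, acrosome and round spermatids, nuclear condensation, sperm tail and late spermatids, the piRNA pathway and protein turnover of late spermatids. Lists for other cells covered general and androgen regulated Sertoli genes, the blood-testis barrier, Leydig cells, peritubular myoid cells, vascular endothelium, macrophages, epididymis and blood. The remaining lists covered immediate early genes, heat shock, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis and autosomal retrocopies of X-linked genes. Of the entries, 66 had no measured gene of that name. The blood list had 2 of its 10 genes measured, under the minimum of 5, and was not tested. All measured X-linked and Y-linked genes formed 2 further lists.

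Named genes followed a rule. For a group, it took the 10 genes with the largest difference higher and the 5 lower among genes past the threshold whose 2 samples both lay beyond all 10 other samples. For a neighbouring step it took the 5 largest in each direction among genes past the threshold whose samples did not overlap. Symbols of predicted genes, receptor families and small RNAs were passed over. The prefix Rn was read as that of small RNAs only, so Rnf and Rnase genes were kept. List examples are members with the widest range among those past the F test, and every retinoid member past it. Members named beside a count because they passed a contrast, or because they did not pass the F test, fall outside the rule and were chosen after their values were seen, as were other genes said to be so in the text.

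Each procedure was tested on simulated data with 19946 genes, 200 of them changed. All 200 were changed in VIII-IX alone, and each gene had the same spread in every group. The recovery rates hold for that setting. Changes in other groups, groups that differ in spread and a larger share of changed genes were not simulated. The F test recovered 16% of genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls among 161. The contrast of VIII-IX with the other groups recovered 68%, 94% and 100%, with 12 false calls among 193. The step from VII to VIII-IX recovered 40%, 90% and 100%, with 13 false calls among 178. With 1 list shifted by 0.3 log2 in 1 group, camera called 5 of 168 list and group pairs, the shifted pair among them. The other called pairs had not been shifted as lists. Simulated genes were drawn independently of each other, so camera was not tested on correlated genes.

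The alternatives were quantile normalization repeated on the table, centring on array medians, leaving out the dimmest 30% of probe sets, the mean of a gene's probe sets, an intensity trend in the prior variance, array quality weights, the sample number as a block, a required 2-fold change, a cosine over the cycle, and leaving out each array. For lists, camera with an estimated correlation and fry were also run. A fit without an array leaves a lone sample that is assumed to vary like the samples of the other groups. A step between groups that keep all their arrays has the same difference in such a fit. Only its estimated spread changes, and alike for either array of the reduced group. Leaving out VIII-IX sample 2 and IX-XI sample 2 together was added after the data were seen. No other pair of arrays was left out together. A loss of calls there thus cannot be told from the loss of residual degrees of freedom. The median difference of genes of like intensity was taken in 50 bins of mean intensity. Principal components were computed on the log2 values of all genes, and their order around the circle was tested with 100000 permutations of the group labels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.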

Results

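Gene expression was measured in 12 adult mouse testis samples whose spermatogenesis had been synchronized, 2 in each of 6 groups that together cover the cycle of the seminiferous epithelium. In a normal testis, tubules at all stages lie side by side. After synchronization, most tubules of a testis share neighbouring stages, so a whole-testis array reads a part of the cycle. The comparisons asked which transcripts change as the cycle runs from XII-I through II-IV, IV-VI, VII and VIII-IX to IX-XI. Levels are log2 intensities, with the SD over 2 samples. The median intensity per array lay between 296.9 and 309.1, and the number of arrays limits the precision of all values.

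The arrays formed a ring in the order of the cycle. The first principal component held 43.6% of the variance and the second 35.4%. Going around the circle from XII-I sample 1, the arrays followed the labelled order through VII sample 2. After it came IX-XI sample 2, VIII-IX sample 1, IX-XI sample 1 and VIII-IX sample 2. The circular agreement of angle and labelled order was 0.838, with p = 0.00015 in a permutation test of 100000 label orders. Samples of a group correlated across genes at 0.987 to 0.995. Of the 12 arrays, 9 lay closer to an array of a neighbouring group than to their partner. Among them, XII-I sample 2 and II-IV sample 2 correlated at 0.998, and II-IV sample 1 and IV-VI sample 2 at 0.998. Genes are not independent replicates in these correlations.

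**Figure D1:**
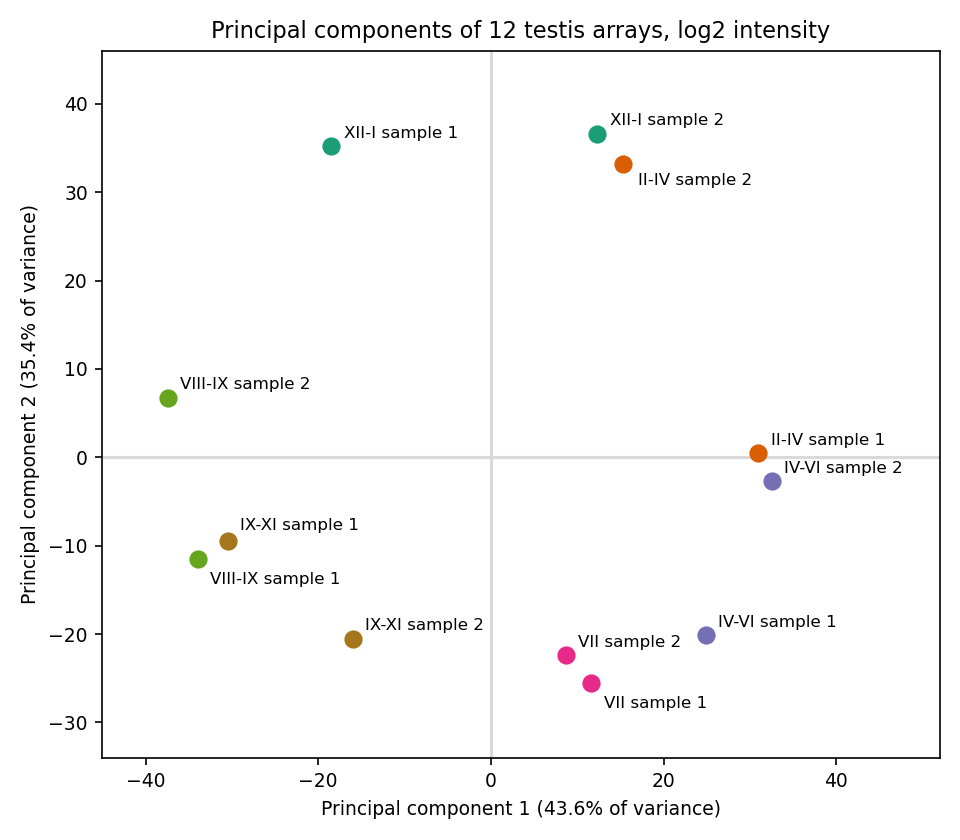
Scores of the 12 arrays on principal components 1 and 2, without units, computed from log2 intensities; each point is an array and each colour a stage group. The arrays surround the origin in cycle order, except that VIII-IX sample 2 lies beyond both IX-XI arrays and IX-XI sample 2 lies before both VIII-IX arrays.

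The widest range over the cycle was that of Spam1. Spam1 (probe set 10536729), which encodes the sperm hyaluronidase, was 17.8-fold higher in IV-VI, at 11.24 ± 0.03 (SD, n = 2), than in VIII-IX, at 7.08 ± 0.95. Faiml was 14.5-fold higher in VIII-IX, at 10.72, than in II-IV, at 6.87. Tssk5, of the testis-specific serine kinases, ranged 13.1-fold and was highest in IV-VI. Cd109 ranged 13.1-fold and was highest in IX-XI. In limma's F test, 3973 of 19946 genes (19.92%) differed among the 6 groups at an adjusted p under 0.05. Of these, 1496 ranged at least 2-fold and 262 at least 4-fold, with a median range of 0.86 log2. Of the 3973, 1266 (31.9%) were highest in XII-I, 810 (20.4%) in VIII-IX, 659 (16.6%) in IV-VI, 520 (13.1%) in II-IV, 501 (12.6%) in IX-XI and 217 (5.5%) in VII. Over all genes, whether or not they passed, the shares were 22.6% in XII-I, 14% in VIII-IX, 12.8% in IV-VI, 10.3% in II-IV, 27.3% in IX-XI and 12.9% in VII. The XII-I count fell to 652 without XII-I sample 1, below the 977 then highest in VIII-IX, to 784 without VII sample 1, and to between 487 (IV-VI sample 1) and 565 (IX-XI sample 1) without either IV-VI sample, VII sample 2, either VIII-IX sample or either IX-XI sample. Its share ranged from 22.9% without XII-I sample 1 to 36.6% without IX-XI sample 1. The share in VIII-IX ranged from 10.7% without VIII-IX sample 1 to 34.3% without XII-I sample 1, that in IX-XI from 9.3% without IX-XI sample 1 to 22.5% without VIII-IX sample 1, that in IV-VI from 6.9% without VIII-IX sample 2 to 20.4% without II-IV sample 1, that in II-IV from 10.7% without XII-I sample 1 to 19.8% without IV-VI sample 2, and that in VII from 1.6% without IV-VI sample 2 to 21.9% without VII sample 1. The count of genes past the F test fell to 1645 without IV-VI sample 1, 1594 without IV-VI sample 2, 1983 without VII sample 2, 1522 without VIII-IX sample 1, 1555 without VIII-IX sample 2, 1544 without IX-XI sample 1 and 1728 without IX-XI sample 2. It was 19 without VIII-IX sample 2 and IX-XI sample 2 together, and 896 genes (22.6%) passed with all 12 arrays and without each array in turn.

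Genes of retinoid uptake, metabolism and signalling were of interest because the synchronization acts through retinoic acid. Rdh10 (probe set 10344952), which oxidizes retinol to retinal, was 4.96-fold higher in IX-XI, at 11.38 ± 0.10 (SD, n = 2), than in II-IV, at 9.07 ± 0.26. Stra6 (10585803), the receptor for retinol bound to its carrier, was 2.93-fold higher in IX-XI, at 9.73 ± 0.13, than in II-IV, at 8.18 ± 0.07. Stra8 (10537231), a gene induced by retinoic acid in germ cells, was 2.53-fold higher in IX-XI, at 8.40 ± 0.09, than in II-IV, at 7.07 ± 0.16. VIII-IX lay near IX-XI for Stra8, at 8.39 ± 0.12, and for Rdh10, at 11.26 ± 0.17. Adh7 (10496425), an alcohol dehydrogenase that can use retinol, and Crabp1 (10585438), a cellular retinoic acid binding protein, were highest in II-IV. Adh7 was 4.56-fold higher there than in VIII-IX, and Crabp1 was 1.83-fold higher there than in IX-XI. Of the other members, Rxra was highest in IX-XI with a range of 2.50-fold, Dhrs4 in XII-I with 2.36-fold, Rxrg in VIII-IX with 2.25-fold, and Cyp26a1, which degrades retinoic acid, in VIII-IX with 1.82-fold. As a whole the list was called in no group, with adjusted p in camera from 0.45 in IV-VI to 0.98 in IX-XI. In limma's F test 9 of the 33 measured members passed (27.3%, against 19.92% of all genes), and 10 adjusted over the list alone. Members that did not pass included the retinal dehydrogenases Aldh1a1 (adjusted p = 0.28) and Aldh1a2 (adjusted p = 0.12), the esterifying enzyme Lrat (adjusted p = 0.085) and the receptor Rara (adjusted p = 0.33), all 4 chosen after their values were seen. Rdh10, Adh7, Stra6, Stra8 and Crabp1 passed whichever array was left out. Of the 12 leave-outs, Rxra passed in 5, Dhrs4 in 7, Cyp26a1 in 6 and Rxrg in 4. Every retinoid call of the F test was lost when VIII-IX sample 2 and IX-XI sample 2 were both left out. No other pair of arrays was left out together, so the loss cannot be laid to these arrays alone.

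**Figure D2:**
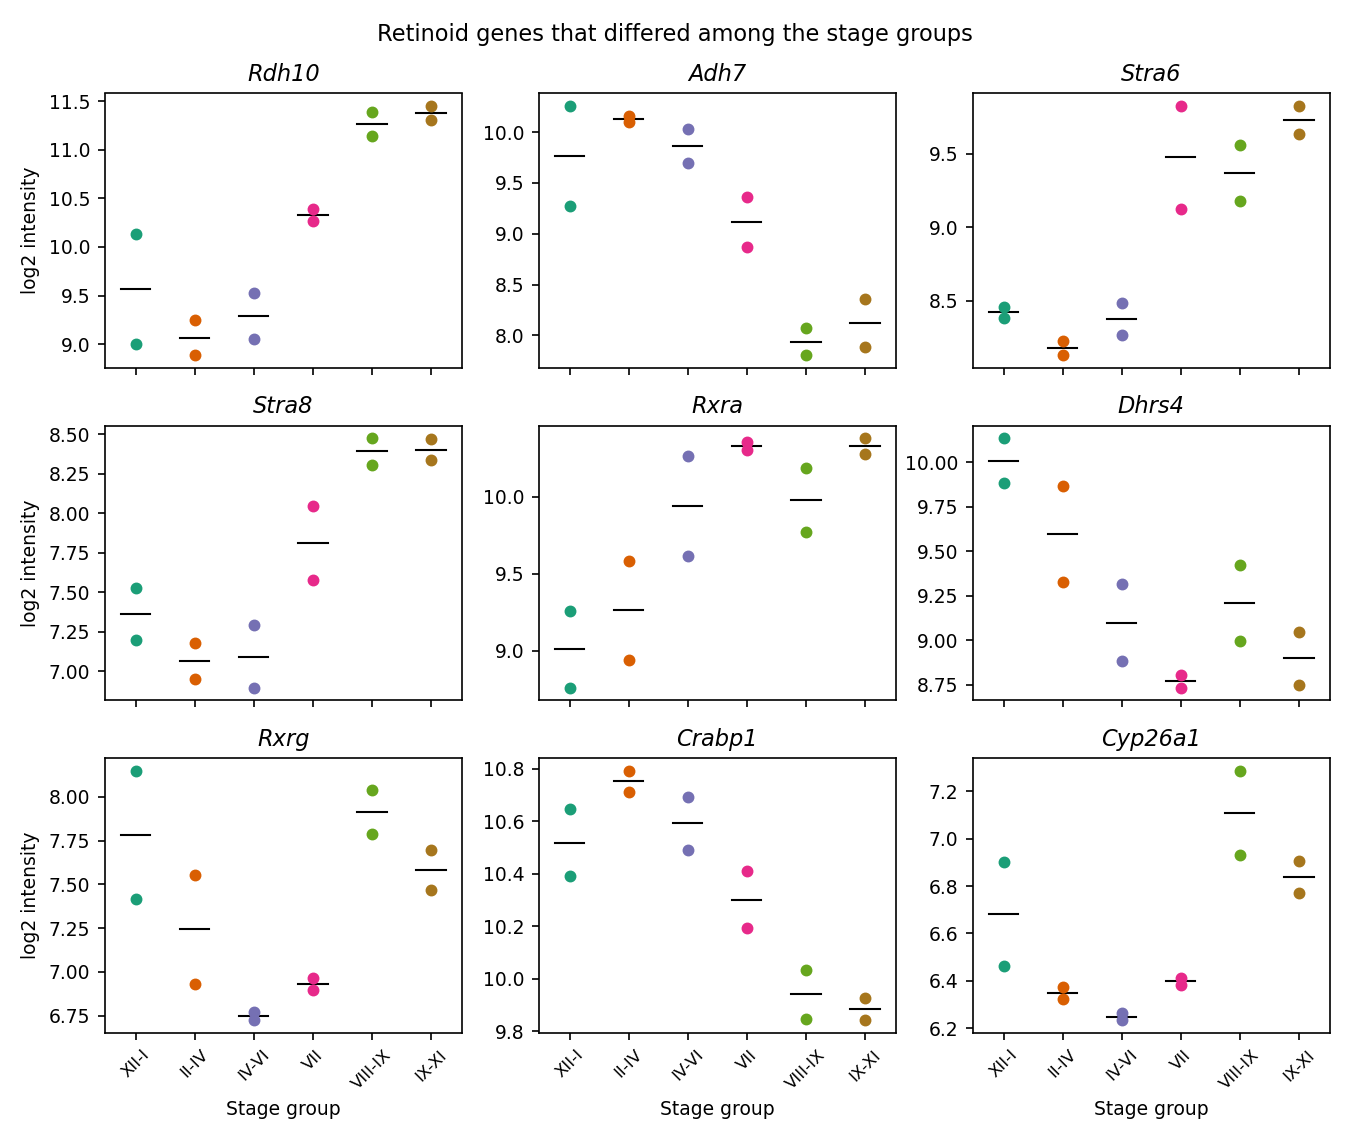
Log2 intensity of the 9 retinoid genes that passed the F test, by stage group; each point is an array and each bar the mean of 2 arrays. Rdh10, Stra6 and Stra8 have their highest means in IX-XI and lowest in II-IV, and Adh7 and Crabp1 have their highest means in II-IV and their lowest in VIII-IX and IX-XI; the vertical axes differ between panels and do not start at 0.

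XII-I, which holds the meiotic divisions in the textbook description of the cycle, had high levels of genes of cell division. Of 43 measured members of the meiotic division and M phase list, 28 passed the F test and 36 adjusted over the list alone, and 21 of the 28 were highest in XII-I. Cenpe (probe set 10496204), a kinetochore motor, was 3.66-fold higher in XII-I, at 10.97 ± 0.09 (SD, n = 2), than in IX-XI, at 9.10 ± 0.04. Plk1 (10557156), a kinase of mitotic and meiotic entry, was 3.63-fold higher in XII-I, at 12.33 ± 0.02, than in IX-XI, at 10.47 ± 0.36. Aurka was 3.57-fold and Ccna1, the cyclin of meiotic male germ cells, 2.94-fold higher in XII-I than in VII. Both Cenpe and Plk1 passed whichever array was left out, as did 9 members of the list in all. Against the mean of the other groups, 26 members rose in XII-I, 1 fell (Mad2l1, by 0.30 log2, named after its values were seen) and the rest did not pass in limma's test (31 higher and 2 lower adjusted over the list alone). The median difference of the list in XII-I was 0.476 log2, with 39 of 43 members higher (camera, adjusted p = 1.5e-10; adjusted p = 1 with an estimated correlation). It was 0.325 log2 without XII-I sample 1. The median deviation from the mean of all arrays was 0.601 log2 on XII-I sample 1 and 0.282 on XII-I sample 2. On II-IV samples 1 and 2 it was 0.114 and 0.280. The list was also higher in II-IV (median 0.183, adjusted p = 4.5e-05), and lower in VII (median -0.300, adjusted p = 2.7e-05) and IX-XI (median -0.273, adjusted p = 1.2e-09), each with adjusted p = 1 with an estimated correlation. The median in II-IV was 0.325 without II-IV sample 1 (adjusted p = 2.8e-05). That in IX-XI was -0.170 without IX-XI sample 2 (adjusted p = 1.2e-05) and -0.158 with VIII-IX sample 2 also left out (adjusted p = 1.7e-05).

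Acrosomal genes were low in XII-I. Of 42 measured members of the acrosome and round spermatid list, 17 fell in XII-I against the other groups, 4 rose and 21 did not pass (23 lower and 6 higher adjusted over the list alone). Lyzl6, a lysozyme-like acrosomal protein, was lower in XII-I by a log2 difference of -1.84 ± 0.40 (SE, n = 2 against 10). Sun5, which joins the sperm head to the tail, differed by -1.40 ± 0.32, and Spaca4, a sperm acrosome membrane protein, by -1.41. The list's median difference was -0.468 log2 in XII-I (camera, adjusted p = 1.6e-06), 0.304 in IV-VI (adjusted p = 5.5e-07) and 0.233 in VII (adjusted p = 8.1e-04). All 3 had adjusted p = 1 with an estimated correlation. The VII call ended without VII sample 1, with a median of 0.139 and adjusted p = 0.57 (1.2e-07 to 0.57 over the 16 normalization, filter, block and leave-out alternatives). In limma's F test, 17 members passed (34 adjusted over the list alone) and 8 of them were highest in IV-VI. Lyzl6 and Sun5 kept that call in 3 of 12 leave-outs each.

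Of the 33 retinoid genes, Dhrs4 rose in XII-I and Rxra and Stra6 fell (1 higher and 1 lower adjusted over the list alone). Among the genes higher there than in the mean of the other 5 groups, Nutm2 was 4.16-fold higher, at 8.94 ± 0.04 (SD, n = 2), with adjusted p = 0.021 in limma. Dnaic2, a dynein chain of motile cilia and flagella, was 3.48-fold higher, Rhcg, an ammonium transporter, 3.00-fold, and Tuft1 2.96-fold. Slc2a8, a glucose transporter, was 2.72-fold higher, Spdye4a 2.66-fold, Epha7, an ephrin receptor, 2.61-fold, Mapk11, a p38 kinase, 2.56-fold, Rfx8 2.50-fold and Cntfr, the receptor of ciliary neurotrophic factor, 2.42-fold. Lower in XII-I were Hsfy2 by 6.48-fold, Adam29 by 6.03-fold, Asb15 by 5.79-fold, Samt3 by 5.21-fold and Cldn34c4 by 4.93-fold. In all, 1497 genes were higher and 664 lower in XII-I in limma's test, but 95 higher and 181 lower among those that differed at least 2-fold. The total of 2161 became 0 without XII-I sample 1, 442 without XII-I sample 2, 3276 without II-IV sample 2, 750 without IV-VI sample 1, 1398 without VII sample 1, 1002 without VIII-IX sample 1, 644 without IX-XI sample 2, 0 without VIII-IX sample 2 and IX-XI sample 2 together, and 552 with array quality weights.

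In VIII-IX, 6 of the 33 measured members of the meiotic initiation list passed limma's test, and the list as a whole did not. Its median difference was 0.065 log2, with 18 of 33 members higher (camera, adjusted p = 0.15). Rad21l, a meiotic cohesin, was higher there than in the other groups by 1.18 ± 0.16 log2 (SE, n = 2 against 10), Prdm9, which marks recombination sites, by 0.88, Stra8 by 0.85 and Dmc1, a recombinase, by 0.73. Of the members, 5 rose, 1 fell and 27 did not pass (10 higher and 5 lower adjusted over the list alone). The member that fell was Rec8, a meiotic cohesin, by 1.41 log2. Of the 33 retinoid genes, Rdh10, Stra8 and Cyp26a1 rose and Adh7 and Crabp1 fell (6 higher and 3 lower adjusted over the list alone). Of 26 undifferentiated spermatogonia genes, Pou5f1 and Lhx1 rose and 0 fell (2 higher and 0 lower adjusted over the list alone; 6 members at an unadjusted p under 0.05 in limma). Pou5f1, a pluripotency transcription factor whose probe set may also read related copies, was 3.80-fold higher in VIII-IX, at 8.42 ± 0.56 (SD, n = 2), than in II-IV, at 6.49 ± 0.18. Of the 16 differentiating spermatogonia genes, Stra8 rose and Sohlh2, Ccnd1 and Dazl fell (3 higher and 5 lower adjusted over the list alone). Of 43 M phase genes, 8 fell, among them Cenpe by 0.72 log2 and Cdc25c by 0.87, and 0 rose. Adjusted over the list alone, 9 were lower and 3 higher, and 18 members had an unadjusted p under 0.05 in limma. The M phase list as a whole was not called, with a median of -0.025 log2 and 19 of 43 members higher (camera, adjusted p = 0.71). Of 39 blood-testis barrier and junction genes, 6 fell, led by Aqp8, and Cldn13 and Cdh2 rose (9 lower and 4 higher adjusted over the list alone), with a list median of -0.127 log2 (camera, adjusted p = 0.20).

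The lists of spermatid nuclear condensation and of the sperm tail were also higher in VIII-IX. Tnp1 and Tnp2, the transition proteins that replace histones, had their highest means in VIII-IX. Tnp1 was 7.01-fold higher there, at 13.01 ± 0.03 (SD, n = 2), than in IV-VI, at 10.20 ± 0.64, and Tnp2 3.54-fold. Their F test calls were kept in 4 of 12 leave-outs for Tnp1 and 5 for Tnp2. The protamines Prm1 (adjusted p = 0.082) and Prm2 (adjusted p = 0.36), chosen after their values were seen, did not pass. Of 14 measured members of the nuclear condensation list, 5 passed the F test (10 adjusted over the list alone), 4 of them highest in VIII-IX. The list's median was 0.380 log2 higher in VIII-IX, with 13 of 14 members higher (camera, adjusted p = 3.8e-04), while 0 of its members passed singly in limma and 8 had an unadjusted p under 0.05. It was -0.261 in IV-VI (adjusted p = 0.013). Both had adjusted p = 1 with an estimated correlation. In IX-XI the list was not called, but its median was 0.280 log2 with 11 of 14 members higher (camera, adjusted p = 0.25). The median deviation from the mean of all arrays was 0.413 and 0.185 log2 on VIII-IX samples 1 and 2. On IX-XI samples 1 and 2 it was 0.290 and 0.117. The VIII-IX call ended without VIII-IX sample 1 (median 0.248, adjusted p = 0.078; 2e-05 to 0.078 over the same kinds of alternative), and the IV-VI call without XII-I sample 1 (adjusted p = 0.062) or VIII-IX sample 1 (adjusted p = 0.063; 9.6e-04 to 0.063 over these). The sperm tail list of 53 genes was 0.131 log2 higher in VIII-IX (camera, adjusted p = 0.013; adjusted p = 1 with an estimated correlation). Its median was 0.076 without II-IV sample 2 (adjusted p = 0.023). Its call ended without VII sample 2 (adjusted p = 0.067), without VIII-IX sample 1 (median 0.091, adjusted p = 0.41), with repeated quantile normalization (median 0.076, adjusted p = 0.27) and without the dimmest 30% of probe sets (adjusted p = 0.057), over a range of 0.0014 to 0.41 in these alternatives. Of its members, Spata19 rose and 4 fell, among them Fsip1 by 1.75 log2 and Tekt4 by 0.73 (7 higher and 7 lower adjusted over the list alone).

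By size, Faiml led the genes higher in VIII-IX, at 5.35-fold above the mean of the other groups (10.72 ± 0.13, SD, n = 2; adjusted p = 0.024 in limma). It was followed by the serine proteases Prss58 (2.92-fold) and Prss51 (2.84-fold), Defb33, a beta-defensin (2.85-fold), Fbxo39 (2.72-fold) and Tfam, the mitochondrial transcription factor (2.70-fold). Tm4sf19 was 2.67-fold higher, Hmgb1-rs17 2.65-fold, Cstl1 2.64-fold and Odf3b 2.63-fold. These folds are against the mean of the other groups, and a neighbouring group could lie near. Faiml was at 10.36 in IX-XI, and Defb33 at 11.69 in VIII-IX, 11.06 in IX-XI and 11.48 in XII-I. At the step from VIII-IX to IX-XI, 0 genes passed. Lower were Mroh9 by 6.21-fold, Atp10a, a phospholipid flippase, by 6.17-fold, Phf8-ps by 5.50-fold, Aqp8, a water channel, by 5.36-fold and Tpte by 5-fold. In all, 705 genes were higher and 859 lower, a share of 45.1% higher that was 83.8% without VIII-IX sample 2, 53% without XII-I sample 1 and 50% without XII-I sample 2. The total of 1564 became 0 without VIII-IX sample 1, 173 without VIII-IX sample 2, 1011 without IV-VI sample 1, 687 without IV-VI sample 2, 617 without IX-XI sample 2, 2711 without XII-I sample 1, 36 without VIII-IX sample 2 and IX-XI sample 2 together, and 386 with array quality weights.

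In IX-XI, 5 of the 33 retinoid genes passed in limma, 3 higher and 2 lower. Rdh10 was higher than in the other groups by 1.48 ± 0.24 log2 (SE, n = 2 against 10), Stra6 by 0.96 ± 0.16 and Stra8 by 0.86 ± 0.15. Adh7 fell by 1.24 log2 and Crabp1 by 0.54, and the other 28 members of the 33 did not pass in limma's test (3 higher and 2 lower adjusted over the list alone). Of the 43 M phase genes, 7 fell, among them Plk1 by 1.18 log2 and Cenpe by 1.01, and 0 rose (16 lower and 0 higher adjusted over the list alone; 21 members at an unadjusted p under 0.05 in limma). The largest rises were those of Tmco5b, 3.48-fold higher at 10.78 ± 0.05 (SD, n = 2; adjusted p = 0.029), and Slc29a3, a nucleoside transporter, 2.65-fold. These folds too are against the mean of the other groups, and Tmco5b was at 10.41 in VIII-IX. Arfgef3 was 2.28-fold higher, Crb1, a cell polarity protein, 2.12-fold, Edrf1 2.12-fold, Nid1, a basement membrane protein, 2.03-fold, Tmem161b 2.03-fold, Itpripl1 1.97-fold, Nmur1 1.93-fold and Pstpip2 1.79-fold. Lower were Agtr1a, an angiotensin receptor, by 2.14-fold, Septin14 by 2.10-fold, Hat1, a histone acetyltransferase, by 1.94-fold, Pls3 by 1.92-fold and Wfdc6a by 1.91-fold. In all, 378 genes were higher and 358 lower, a share of 51.4% higher that was 41.1% with arrays centred on their medians, 49.5% without the dimmest 30% of probe sets, 43% without VII sample 1 and 46.9% without VII sample 2. The total of 736 became 0 without IX-XI sample 1, 0 without IX-XI sample 2, 297 without IV-VI sample 2, 1265 without XII-I sample 1, 0 without VIII-IX sample 2 and IX-XI sample 2 together, and 2428 with array quality weights.

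Y-linked genes were low in IX-XI and also in VIII-IX. In VIII-IX the list median was -0.155 log2, and the list was not called (camera, adjusted p = 0.27). In limma, 2 of the 9 genes were lower and 0 higher in each of these groups, and the rest did not pass. The lowest median deviation was on VIII-IX sample 2, at -0.274 log2. In IX-XI, Srsy, a multicopy Y gene whose copies the probe set may not separate, was lower by 1.17 log2 and Uty by 0.38 (camera median -0.180, adjusted p = 0.030; adjusted p = 1 with an estimated correlation). That call ended without XII-I sample 1 (adjusted p = 0.054), VIII-IX sample 1 (adjusted p = 0.052) or IX-XI sample 1 (adjusted p = 0.10) and without the dimmest 30% of probe sets (adjusted p = 0.10), over a range of 0.0063 to 0.10 in the normalization, filter, block and leave-out alternatives.

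No gene passed in the contrasts of II-IV, IV-VI and VII with the other groups. The limma counts were 0 in each, with 3430 genes at an unadjusted p under 0.05 in II-IV, 4060 in IV-VI and 3963 in VII. The contrasts of XII-I, VIII-IX and IX-XI, built in the same way, had 5332, 4968 and 4397 genes at that unadjusted p. The lowest adjusted p in limma was 0.065 in II-IV, 0.060 in IV-VI and 0.11 in VII. With the sample number as a block, 749 genes passed in II-IV and 4 in IV-VI. Genes highest in II-IV, IV-VI or VII still passed the F test without the block. Sohlh2 and Dazl, of the differentiating spermatogonia list, were highest in II-IV, at 9.80 ± 0.04 (SD, n = 2) and 11.95 ± 0.10. Rec8 was highest in IV-VI, at 10.94 ± 0.05, and Eppin, an androgen regulated protease inhibitor of Sertoli cells, in VII, at 11.85 ± 0.15. Eppin kept its F test call in 2 of 12 leave-outs, Rec8 in 5, Dazl in 11 and Sohlh2 in 12. II-IV gave 321 genes without XII-I sample 1, 1218 without XII-I sample 2, 4 without IV-VI sample 2 and 3 without VIII-IX sample 2. IV-VI gave 1311 without II-IV sample 1, 79 without II-IV sample 2, 2 without XII-I sample 1, 1381 without XII-I sample 2, 13 without VIII-IX sample 2 and 3034 with array quality weights. VII gave 981 without II-IV sample 1 and 778 without VII sample 1.

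**Figure D3:**
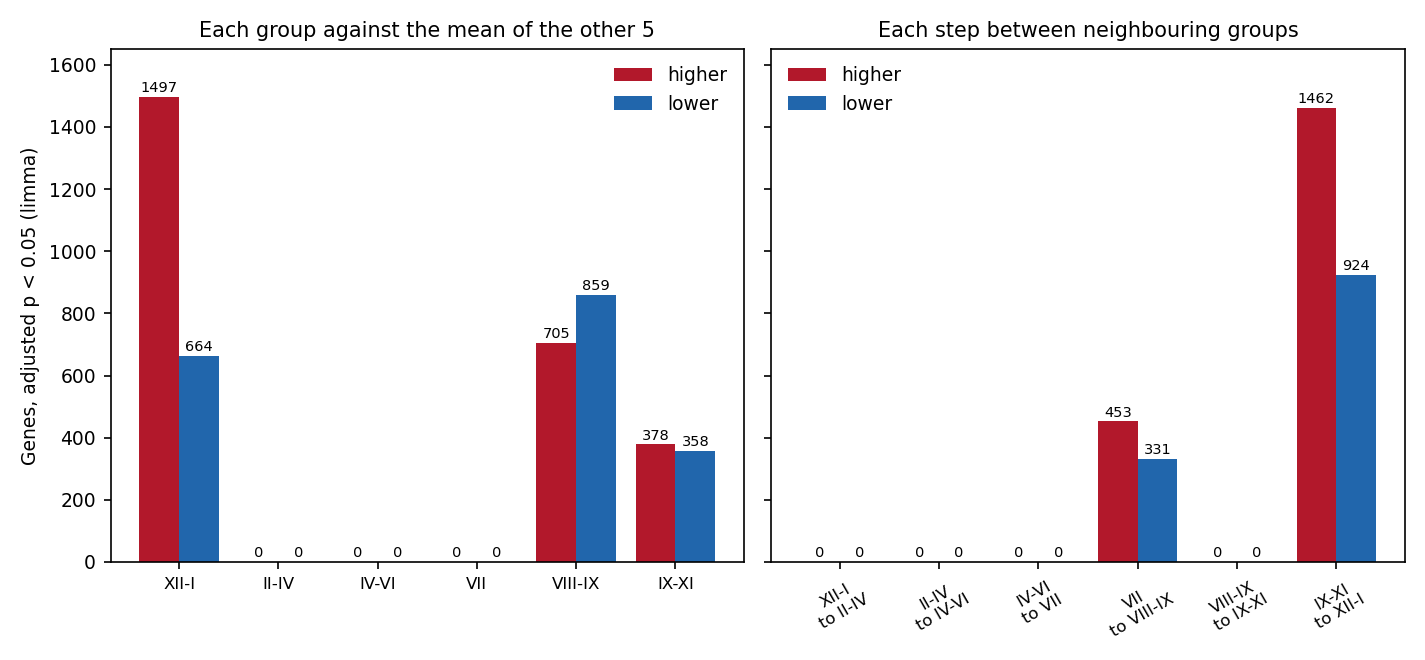
Number of genes higher (red) and lower (blue) at an adjusted p under 0.05 in limma, for each group against the mean of the other 5 (left) and for each step from a group to the next (right); the vertical axis counts genes of 19946 tested. Calls occur in XII-I, VIII-IX and IX-XI and at the steps from VII to VIII-IX and from IX-XI to XII-I, with 0 elsewhere.

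In VII, the macrophage, Leydig and 2 Sertoli lists were high, and the calls rested on VII sample 2. The other lists of cells outside the germ line were not called: the median was 0.078 log2 for myoid cells (camera, adjusted p = 0.095), -0.002 for endothelium (adjusted p = 0.87) and -0.064 for epididymis (adjusted p = 0.25). Macrophage genes had a median difference of 0.315 log2 against the other groups, with 17 of 18 higher (camera, adjusted p = 5.3e-04). Leydig cell genes had 0.319, with 11 of 11 higher (adjusted p = 8.8e-05), general Sertoli genes 0.155 (adjusted p = 6.8e-05) and androgen regulated Sertoli genes 0.231 (adjusted p = 0.013). Immediate early genes had 0.199 (adjusted p = 8.1e-04), ribosomal protein genes 0.023 (adjusted p = 0.031) and X-linked genes 0.025 (adjusted p = 0.0020). All 7 had adjusted p = 1 with an estimated correlation. Without VII sample 2, all 7 calls ended: the median was -0.122 for macrophages (adjusted p = 0.15), 0.151 for Leydig cells (adjusted p = 0.16), -0.010 for general Sertoli genes (adjusted p = 0.69), 0.126 for androgen regulated Sertoli genes (adjusted p = 0.30), -0.022 for immediate early genes (adjusted p = 0.50), 0.029 for ribosomal proteins (adjusted p = 0.19) and -0.019 for X-linked genes (adjusted p = 0.40). Without VII sample 1 the medians were 0.804 for macrophages, 0.504 for Leydig cells, 0.327 for general Sertoli genes, 0.354 for androgen regulated Sertoli genes, 0.343 for immediate early genes, 0.051 for ribosomal proteins and 0.045 for X-linked genes. The X-linked median was 0.118 without the dimmest 30% of probe sets (adjusted p = 2.6e-05) and 0.040 with repeated quantile normalization. The ribosomal median was 0.041 without XII-I sample 1, 0.035 without II-IV sample 1 or IV-VI sample 1, 0.040 without VIII-IX sample 1 and 0.039 without IX-XI sample 1. The calls also ended with fry, with adjusted p from 0.25 for androgen regulated Sertoli genes to 0.66 for macrophages. The ribosomal call also ended without XII-I sample 2 (adjusted p = 0.053), IV-VI sample 1 (adjusted p = 0.055), VIII-IX sample 2 (adjusted p = 0.061) or IX-XI sample 2 (adjusted p = 0.069), with repeated quantile normalization (adjusted p = 0.065) and without the dimmest 30% of probe sets (adjusted p = 0.14), and with VIII-IX sample 2 and IX-XI sample 2 both left out (adjusted p = 0.12). Lyz2, a macrophage lysozyme chosen after its values were seen, had a log2 intensity of 11.07 in VII sample 2 and 9.25 in VII sample 1.

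**Figure D4:**
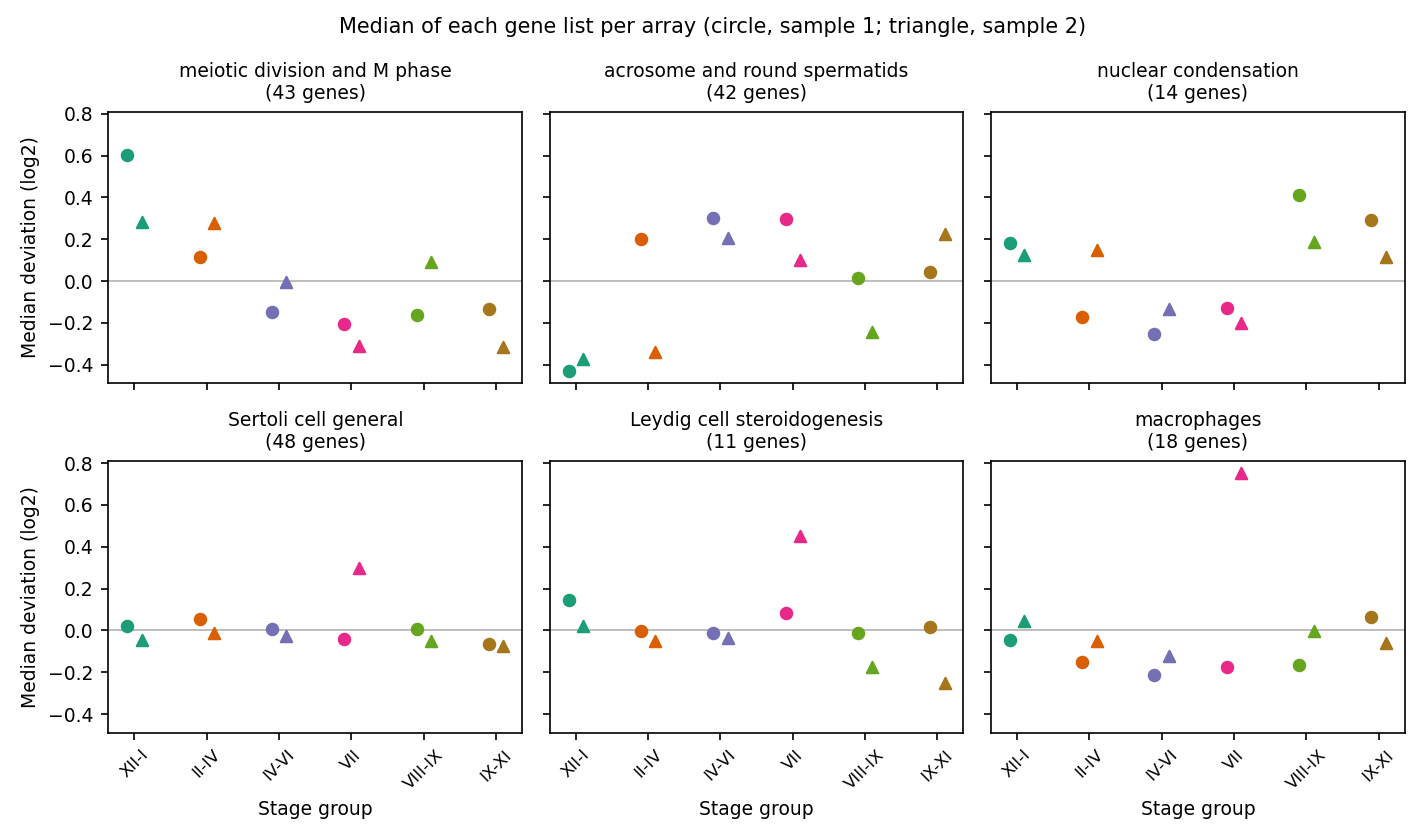
Median over the genes of 6 lists of each gene's deviation from its mean over the 12 arrays (log2), by stage group, with sample 1 as circles and sample 2 as triangles. M phase genes are highest on XII-I sample 1 (0.601), and macrophage (0.752), Leydig (0.451) and general Sertoli genes (0.299) are highest on VII sample 2.

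At the step from VII to VIII-IX, Spam1 was the 1 gene of the 42 in the acrosome list that passed. It fell 14.5-fold, from 10.94 ± 0.26 (SD, n = 2) to 7.08 ± 0.95, with adjusted p = 0.043 in limma. Aqp8 fell 9.71-fold, Serpina3a, a serpin, 9.34-fold, Fam186a 8.82-fold and Tssk5 8.56-fold. Pou5f2, a POU domain factor, rose 6.20-fold, Klk1b5, of the kallikreins, 5.52-fold, Defb33 5.21-fold, Gramd2 4.63-fold and Odf3b 4.55-fold. Of 33 meiotic initiation genes, Rad21l and Dmc1 rose and Rec8 fell (6 higher and 2 lower adjusted over the list alone). Of 39 blood-testis barrier and junction genes, Aqp8, Jam2 and Ctnnb1 fell and 0 rose (6 lower and 3 higher adjusted over the list alone). The VII samples differed in this list, with a median deviation from the mean of all arrays of 0.094 log2 on VII sample 2 and -0.051 on VII sample 1, against 0.299 and -0.043 for general Sertoli genes. Jam2, chosen after its values were seen, was at 11.25 on VII sample 2, 10.47 on VII sample 1 and 9.70 in VIII-IX. Of 33 retinoid genes, Cyp26a1 rose and 0 fell (3 higher and 1 lower adjusted over the list alone). Of 26 undifferentiated spermatogonia genes, Lhx1 and Pou5f1 rose and 0 fell (2 higher and 1 lower adjusted over the list alone). In all, 453 genes rose and 331 fell, a share of 57.8% rising. Leaving out an array of a group outside this step keeps the difference of means and changes only the estimated spread. Either array of such a group therefore gives the same fit for this step, not a separate check. With the sample number as a block, 260 genes passed, 70.8% of them rising. Without VII sample 1 the balance turned, with 27.9% of 1015 genes rising, and 314 of the 784 genes were among them. The total of 784 became 0 without either IV-VI sample, VII sample 2 or VIII-IX sample 1, 20 without VIII-IX sample 2, 37 without either IX-XI sample, 1657 without either XII-I sample and 1678 without either II-IV sample. It was 0 without VIII-IX sample 2 and IX-XI sample 2 together, 11 with array quality weights and 1187 without the dimmest 30% of probe sets.

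At the step from IX-XI to XII-I, many division genes rose, and the retinoid genes that passed moved both ways. Of 43 M phase genes, 21 rose, 0 fell and 22 did not pass in limma's test (32 higher and 1 lower adjusted over the list alone). Cenpe led at 1.87 log2, with Plk1 at 1.86. Lists were not tested as a whole on the steps. Of 33 retinoid genes, Rdh10, Rxra, Stra6 and Stra8 fell and Adh7, Dhrs4 and Crabp1 rose (4 lower and 3 higher adjusted over the list alone). Rdh10 fell by 1.81 log2 and Adh7 rose by 1.64. Of 42 acrosome genes, 10 fell and 5 rose (22 lower and 6 higher adjusted over the list alone). Of 19 cholesterol synthesis genes, Cyp51, which removes a methyl group from lanosterol, and Fdps fell and Idi1, chosen after its values were seen, rose (2 lower and 3 higher adjusted over the list alone). The largest falls were those of Cd109, 13.1-fold, from 10.91 ± 0.14 (SD, n = 2) to 7.20 ± 0.57 (adjusted p = 0.0092), Lrrd1 10.6-fold, Dyrk4, a kinase, 9.96-fold, Slc36a3, an amino acid transporter, 9.57-fold, and Cd46, a complement regulator, 8.57-fold. Nutm2 rose 5.77-fold, Cfap47, a protein of cilia and flagella, 5.20-fold, Iqca 4.72-fold, Prss46 4.58-fold and Alas2, of haem synthesis, 4.47-fold. In all, 1462 genes rose and 924 fell, but 218 rose and 303 fell among those that changed at least 2-fold, and 45.5% of the 11 genes called without IX-XI sample 2 rose. The total of 2386 became 395 without IX-XI sample 1, 11 without IX-XI sample 2, 769 without XII-I sample 2 and 0 without VIII-IX sample 2 and IX-XI sample 2 together.

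The other 4 steps gave 0 genes in limma. The counts at an unadjusted p under 0.05 were 1980 from XII-I to II-IV, 1323 from II-IV to IV-VI, 1183 from IV-VI to VII and 925 from VIII-IX to IX-XI. Without XII-I sample 1, the step from XII-I to II-IV gave 1 gene. Without II-IV sample 1, that from II-IV to IV-VI gave 22. The step from IV-VI to VII gave 393 genes without VII sample 1 and 1 without either XII-I sample, and that from VIII-IX to IX-XI gave 7 without VIII-IX sample 2.

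The counts over the remaining lists are of members past limma's F test, with the count adjusted over the list alone in brackets. Of 28 pachytene and diplotene genes 7 passed (10), with Pou5f2, a POU domain factor, ranging 6.62-fold and highest in VIII-IX, and Calr3, a testis calreticulin, ranging 5.20-fold and highest in IX-XI. Of 26 undifferentiated and 16 differentiating spermatogonia genes 5 (6) and 7 (7) passed, and of 33 meiotic initiation genes 12 (18). Of 43 DNA replication genes 15 passed (19), 7 of them highest in XII-I. Of 53 sperm tail genes 16 passed (21), of 25 genes of late spermatid protein turnover 4 (4), and of 26 piRNA pathway genes 5 (8), among them Tdrd7, highest in II-IV. Of 39 barrier and junction genes 12 passed (14), led by Aqp8 with 10.7-fold. Of 48 general Sertoli genes 10 passed (12), led by Plat, plasminogen activator, with 2.74-fold and highest in VIII-IX, and of 17 androgen regulated Sertoli genes 8 (10). Of 15 heat shock genes 6 passed (9), led by Hsf2, a heat shock factor highest in IV-VI, and of 19 cholesterol synthesis genes 4 (5), led by Cyp51, highest in IX-XI. Of 11 Leydig genes 1 passed (1), of 13 myoid genes 1 (0), of 18 macrophage genes 1 (1), of 15 endothelial genes 2 (2), of 15 epididymal genes 2 (2), of 21 immediate early genes 3 (1), of 35 ribosomal protein genes 1 (0) and of 56 oxidative phosphorylation genes 4 (2). Of 9 autosomal retrocopies 0 passed (0), with 3 at an unadjusted p under 0.05 in limma. Of 739 X-linked genes 150 passed (154) and of 9 Y-linked genes 5 (5), led by Srsy with 4.57-fold and highest in XII-I.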

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

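Leaving out VIII-IX sample 2 and IX-XI sample 2 together was chosen after the data were seen. The count of genes differing among the groups stayed between 3949 and 4628 under repeated quantile normalization, median centring, the dim filter, the mean of probe sets, the variance trend, array weights and the block. A cosine over the cycle gave 5589, of which 3317 were shared. Of 65 named gene results, 64 or 65 kept their call under quantile normalization, centring, the mean of probe sets and the trend, 63 of 63 measured under the dim filter, 41 with array weights and 59 with the block, with 0 reversed. Without single arrays 22 to 65 kept it. With both doubted arrays left out, 0 did; the differing genes were 19, and the calls were 0 in XII-I, 36 in VIII-IX, 0 in IX-XI, 0 from VII to VIII-IX and 0 from IX-XI to XII-I. The cause of these changes was not tested. No other pair of arrays was left out together, and this fit has fewer residual degrees of freedom, so the losses do not show that the results rest on these arrays. With single arrays left out, differing genes ranged from 1522 to 4269, XII-I from 0 to 3276, II-IV from 0 to 1218, IV-VI from 0 to 1381, VII from 0 to 981, VIII-IX from 0 to 2711 and IX-XI from 0 to 1265. The steps ranged from 0 to 1 (XII-I to II-IV), 0 to 22 (II-IV to IV-VI), 0 to 393 (IV-VI to VII), 0 to 1678 (VII to VIII-IX), 0 to 7 (VIII-IX to IX-XI) and 11 to 2771 (IX-XI to XII-I), and called list and group pairs from 13 to 37. Quantile normalization gave 1 gene in II-IV and 1 in IV-VI, the dim filter 2 in IV-VI and 1187 from VII to VIII-IX, and the variance trend 3 in II-IV and 3 in IV-VI. Array weights, equal within a group, gave 552 in XII-I, 3034 in IV-VI, 386 in VIII-IX, 2428 in IX-XI and 11 from VII to VIII-IX. A required 2-fold change left 1496 differing genes, 276 in XII-I, 288 in VIII-IX, 104 in IX-XI, 266 from VII to VIII-IX and 521 from IX-XI to XII-I, since smaller changes were left out. Of 18 called list and group pairs, 0 held with an estimated correlation and 0 with fry. Without VII sample 2 the medians in VII reversed to -0.122 for macrophages, -0.010 for general Sertoli, -0.022 for immediate early and -0.019 for X-linked genes, against 0.804, 0.327, 0.343 and 0.045 without VII sample 1. Median, mean and test had different signs in 0 of these 18 pairs and in 41 of 168.

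The labels do not say whether the sample numbers pair samples across groups, and the values leave this open. Between groups, same-numbered deviations correlated across genes at -0.354 to 0.541, above 0.1 in 7 of 15 group pairs. The average of a group's correlations was above 0 in 5 of 6 groups. With the number as a replicate block, 4147 genes differed, and the calls were 749 in II-IV, 4 in IV-VI, 1166 in IX-XI, 2515 in XII-I, 1936 in VIII-IX, 1 from IV-VI to VII, 260 from VII to VIII-IX and 2801 from IX-XI to XII-I. Called list and group pairs were 20. No array was counted as a duplicate, since no pair within a group was closer than the closest pairs between groups, so that alternative was not run. The deposited table gives intensities alone, so signal over background, and what it limits, could not be measured.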

Other observations

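All tests in this part were chosen after the results were seen, except the test of other splits of the samples. Among genes past the F test, a larger share of X-linked than of autosomal genes was highest in II-IV or IV-VI. Over all 739 measured X-linked genes, the list test fixed beforehand called neither group. The median difference was 0.009 log2 in II-IV (camera, adjusted p = 0.64) and -0.004 in IV-VI (adjusted p = 0.29). Of 150 X-linked genes past the F test, 75 (50%) were highest in II-IV or IV-VI, against 1098 of 3803 autosomal genes (28.9%), an odds ratio of 2.46 with a 95% interval of 1.75 to 3.47 (Fisher's exact test, two-sided, p = 1.3e-07). XII-I held the highest level of 15 of the X-linked genes (10%) and of 1246 autosomal genes (32.8%). These shares were 18.7% and 25.1% without VII sample 2, 16% and 23.2% without XII-I sample 1, and 15.3% and 36.1% without XII-I sample 2. Examples are Cfap47, a protein of cilia and flagella, at 9.86 ± 0.18 (SD, n = 2) in II-IV and 7.11 ± 0.12 in VIII-IX, Alas2, of haem synthesis, at 10.19 ± 0.20 in II-IV and 7.64 ± 0.40 in VIII-IX, and Akap14, an anchor of protein kinase A chosen after its values were seen, at 10.30 ± 0.12 in IV-VI and 8.10 ± 0.68 in VIII-IX. Others ran the other way: Tmem255a, chosen in the same way, was highest in VIII-IX and lowest in IV-VI. The odds ratio was 2.43 after repeated quantile normalization. It was 1.89 without II-IV sample 1, 1.62 without VII sample 1, 5.27 without VIII-IX sample 1, 4.83 without VIII-IX sample 2, 5.74 without IX-XI sample 1 and 4.49 without IX-XI sample 2, and 2.28 to 3.32 without each other array in turn. Genes are not independent replicates, and the groups were picked after their counts were seen.

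The 12 arrays split into 6 pairs in other ways gave fewer differing genes than the labelled groups. Of 100 splits, the labelled one included, 1 gave as many as 3973 genes, the highest other split gave 1298, and 8 of the other splits gave any gene. The labelled count was thus above that of every other split drawn. This does not exclude chance, since the 100 splits are a small part of those possible. Of the 12 arrays, 9 had their nearest array in another group, and splits that pair nearest arrays were not tested on their own.

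The VIII-IX and IX-XI arrays did not follow the labelled order. On the ring of arrays, IX-XI sample 2 stood at 263 degrees, VIII-IX sample 1 at 296.3, IX-XI sample 1 at 297.8 and VIII-IX sample 2 at 325.2. A remaining difference in scaling would move genes of like intensity alike, and is argued against: with the median of genes of like intensity removed, VIII-IX sample 2 minus IX-XI sample 2 correlated across all genes at 0.703 ± 0.0062 (bootstrap SE over genes) with the XII-I mean minus the VII mean. Genes are not independent replicates, so this SE does not measure the spread between samples. An exchange of labels between these arrays stays open: exchanging them changed the mean within-group correlation by -0.001, less than the SD of 0.0036 among the other 4 groups. It cannot be told apart from testes whose tubules differ in how far they had advanced, since no staging of single arrays is given.

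XII-I sample 2 and II-IV sample 2 were the closest pair of arrays, at a correlation of 0.998, with 5 genes differing 2-fold or more, although their groups differ. If the same RNA had been measured under both labels, their difference would be technical. Across the 3973 genes past the F test, which used both arrays, it correlated at 0.523 with the difference of the IV-VI mean from XII-I sample 1. Over all genes the correlation was 0.313. Technical differences that follow intensity were not removed here and could also correlate, so the test leaves this explanation open. Testes at nearly the same point of the cycle remain possible and were not tested.

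VII sample 2 stood apart in markers of some other cells. Against VII sample 1, the median was higher by 1.03 log2 for macrophages (18 of 18 genes), by 0.349 ± 0.243 (bootstrap SE) for Leydig cells, by 0.319 for general Sertoli genes, by 0.259 for myoid cells and by 0.193 for endothelium, and epididymal genes differed by 0.008. Macrophage genes rose more than endothelial genes by 0.837 ± 0.127 log2 (bootstrap SE over genes). An even fall in the share of germ cells would raise both lists alike only if each read its own cells alone. That was not measured, so this value cannot decide about such a fall. A remaining scaling difference is argued against, since the macrophage median was 1.013 ± 0.105 with the median of genes of like intensity removed. A response to handling stays open: immediate early genes were higher by 0.422 ± 0.16, in 14 of 21, but the heat shock and stress list differed by 0.058 ± 0.145, with 9 of 15 higher. Inflammation or more interstitial tissue in this testis may also account for it and was not tested. Lyz2 (11.07 against 9.12 to 9.65 on the other arrays), Cd74 (9.81) and Cyp11a1 (12.30) were each highest on this array. Of other steroidogenic genes, Hsd3b1 was at 9.7 against 8.86 on VII sample 1. Star differed less, at 10.48 against 10.44, as did Cyp17a1, at 12.76 against 12.57. All of these genes were chosen after their values were seen. Of the 18 macrophage and 11 Leydig genes, 0 stand in another fixed list, and of the 48 general Sertoli genes 12 do.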
